A study of Homo sapiens with 2 samples.

How the data were processed

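Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA fragments bound by a protein and counts them along the genome. The series holds 1 p63 ChIP library and 1 input library from JHU-029, an established head and neck squamous cell carcinoma line. Input is sheared chromatin sequenced without antibody, and it measures the local background. Per the labels' protocols, untreated cells were fixed with the protein crosslinker EGS and then with formaldehyde, and chromatin was precipitated with the H129 antibody against p63. Neither library has a replicate, so no value has a replicate error and no test between libraries was made.

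The processed data consist of 1 peak list. Reads were aligned to the human build hg19 with Bowtie 0.12.5 and handled with SAMtools, per the submitters' processing notes. Peaks were called with MACS 2.0.10.20120913 in narrow mode at a q cutoff of 0.01, per the file headers. The headers also give 10380388 ChIP tags and 39302536 input tags of 50 bp with at most 1 tag kept per position, a fragment length of 148 bp, and scaling of the larger library to the smaller. Removing duplicates caps the height of strong peaks and of the input level, and the scaling makes 1 input tag worth 0.264 ChIP tags. The deposited pileup, a signal, is the number of extended ChIP fragments stacked at the summit. The deposited fold enrichment is the pileup plus 1 divided by the local input level plus 1, a ratio that is pulled towards 1 where the pileup is low. The deposited −log10 p and −log10 q values are the peak caller's own scores of ChIP against local background for each peak. Positions are 1-based hg19 positions, as deposited, and each of the 18548 peaks holds its summit.

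The input level behind each peak was recovered from the pileup and the fold enrichment. With these levels a Poisson tail returned the deposited −log10 p of every peak within 0.000122, whereas the same calculation without the added 1 missed it by a median of 3.88. The peak caller takes the largest of 4 background estimates, so the recovered level is an upper estimate of the local input. It was set by the fragment-sized window in 58.1% of peaks, by a 1 kb window in 25.4%, by a 10 kb window in 8.31% and by the genome average in 8.19%. In the fragment-sized windows it rested on a median of 6 input tags (quartiles 4 and 8). Peaks over an input level of 5 scaled tags were treated as a separate set. This limit was chosen after the data were seen.

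Peaks per chromosome were compared with the extent from the first to the last peak, over chromosomes 1 to 22 and X, by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 23 chromosomes. Because peaks cluster, these p-values are too small. The same comparison was therefore repeated by permuting 5-Mb bins between chromosomes (10000 permutations). The expected share was also computed from the number of protein-coding genes per chromosome, counted in a RefSeq table. Arms were split at the largest peak-free stretch of each chromosome, and chromosomes 13, 14, 15, 21 and 22, whose short arms carry almost no assembled sequence, were kept whole. Arm densities were compared by permuting 5-Mb bins within a chromosome, with intervals from resampling bins (1000 draws). Both bin permutations take neighbouring bins as exchangeable, so their p-values are too small where neighbours share a density. Clustering was measured as the share of summits with another within 10 kb, against 1000 shuffles over the chromosome or within 1-Mb windows. Fold enrichments of 2 sets of peaks were compared by a permutation test of medians (100000 resamples). All p-values describe peaks or bins of this 1 list and do not measure the spread between cultures. Intervals of pileups are exact Poisson intervals at 95%. They cover counting error only.

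Peak counts per chromosome, the comparison of chromosomes, its stricter q limit and its gene-based expectation were fixed before the data were examined. The plan set the expectation by chromosome length. The extent from first to last peak, taken from this list, was used in its place. The comparison of arms, the clustering analysis and the input-level sets were added afterwards. On lists simulated with the real number of 17961 peaks on these chromosomes, the chromosome test called 100% of the chromosomes given 1.5 times their share (3 in each of 50 lists). With the simulated shares as its expectation, it called 0.609% of all chromosomes. Simulated peaks were placed independently, so this is not the rate of false calls among clustered peaks. A simulated list with 20% of its summits paired exceeded all of 100 shuffles, and a uniform list was reached by 53 of 100.

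Peaks were to be named by rule: 6 preset genes, the 10 peaks with the largest fold enrichment, and members of 18 gene lists near a summit. No hg19 sequence or annotation was used here, and the RefSeq table gives positions on another build (GRCh38.p14). It served only for gene names, chromosome assignments and gene counts. Peaks are therefore given by position without a gene name, and the planned promoter, motif and gene list comparisons were not run. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.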

Results

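p63 is the product of TP63, a transcription factor of the p53 family that maintains basal cells of squamous epithelia. The series asks where p63 binds in JHU-029 head and neck squamous carcinoma cells, in a study of how p63 and ACTL6A, a subunit of BAF chromatin remodelling complexes, act on the Hippo-YAP pathway. The data are 1 p63 ChIP library of 10380388 tags and 1 input library of 39302536 tags, summarised as peaks of ChIP over input. There are no replicates. Every error below is a counting error, a binomial error of a share of peaks, or the spread between peaks or regions of this list.

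p63 ChIP exceeded input at 18548 peaks, of which 17961 lay on chromosomes 1 to 22 and X. The median peak was 235 bp wide (quartiles 172 and 307 bp) and had a pileup of 18 fragments. Its fold enrichment over input was 8.01, with quartiles of 6.22 and 10.9. A pileup of 18 has a Poisson interval of 10.7 to 28.4, so folds of single median peaks are known only loosely. The weakest peaks rested on 6 fragments. At least 10-fold enrichment was reached by 5806 peaks, or 31.3% of the list (Clopper-Pearson 95% interval, 30.6% to 32.0%). That interval treats peaks as independent draws and leaves out the counting error of their folds. The stricter limit of 10 on the −log10 q scale was passed by 10777 peaks.

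The strongest peak lay on chromosome 12 at 115312219 to 115312546 (hg19), with 109 ChIP fragments at the summit and a fold enrichment of 53.5 (Poisson interval, 44.0 to 64.4). The second, on chromosome 20 at 46110522 to 46110995, was enriched 47.7-fold (38.7 to 58.0). The third, on chromosome 6 at 468916 to 469267, was enriched 45.7-fold (37.8 to 54.6). Chromosome 8 held 3 of the 10 strongest peaks. They lay at 22253871 to 22254208 with 45.3-fold, at 85948906 to 85949143 with 44.5-fold, and at 49621382 to 49621989 with 43.1-fold enrichment. The peak on chromosome 4 at 513336 to 513949 was enriched 44.0-fold, and that on chromosome 1 at 3633569 to 3634488 was enriched 43.6-fold. A further peak on chromosome 20, at 49113263 to 49113638, was enriched 43.3-fold. The seventh strongest peak of the list was on chromosome 3 at 189551742 to 189552162, where 112 fragments gave a 43.7-fold enrichment (36.1 to 52.5).

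These 10 sites could not be ranked by strength at this depth. The upper bound of 37 peaks reached the lower bound of the first, 44.0-fold. The folds also depend on few input tags. The first peak was measured against 4 input tags in its fragment-sized window, and the plain ratio of ChIP to scaled input there was 103, with a counting interval of 39.2 to 385. The peak on chromosome 3 was measured against 6 input tags, with a plain ratio of 70.7 (31.5 to 197).

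A separate set of 852 peaks, 4.59% of the list (4.30% to 4.90%), lay where the input itself was high, above 5 scaled tags. Their median input level was 18.8, against 1.28 in the other 17696 peaks. They were tall, with a median pileup of 60, yet their median fold enrichment was 3.07 against 8.19 in the others. The split itself sets part of this, since the input level divides the fold and the q cutoff demands taller pileups over higher input. Median plain ratios were 14.9 in the others and 3.17 in the high-input peaks. The upper quartile of the latter was 3.79, the number of input tags per ChIP tag. Whether the duplicate cap on the deeper input sets these ratios was not tested. Of the 603 high-input peaks on chromosomes 1 to 22 and X, 376 (62.4%, interval 58.4% to 66.2%) lay within 1 Mb of the longest peak-free stretch of their chromosome, or of the first peak in the acrocentric chromosomes. The share was 1.11% (0.956% to 1.27%) in the other peaks, an odds ratio of 148.1 by Fisher's exact test. These intervals and the test treat peaks as independent, although high-input peaks lay in groups. The stretches are also bounded by peaks of the same list. The limit of 5 was set after the data were seen. At a limit of 3 the set was 8.44% of the list with 29.55% near such stretches, and at 10 it was 3.53% with 81.75%. Among 1-Mb windows of these chromosomes, the most high-input peaks were 55 on chromosome 10 between 42360635 and 42600485, at a median input level of 32.2. Away from such stretches, 32 peaks lay on chromosome 5 between 17517853 and 17632514, at a median input level of 9.90.

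**Figure D1:**
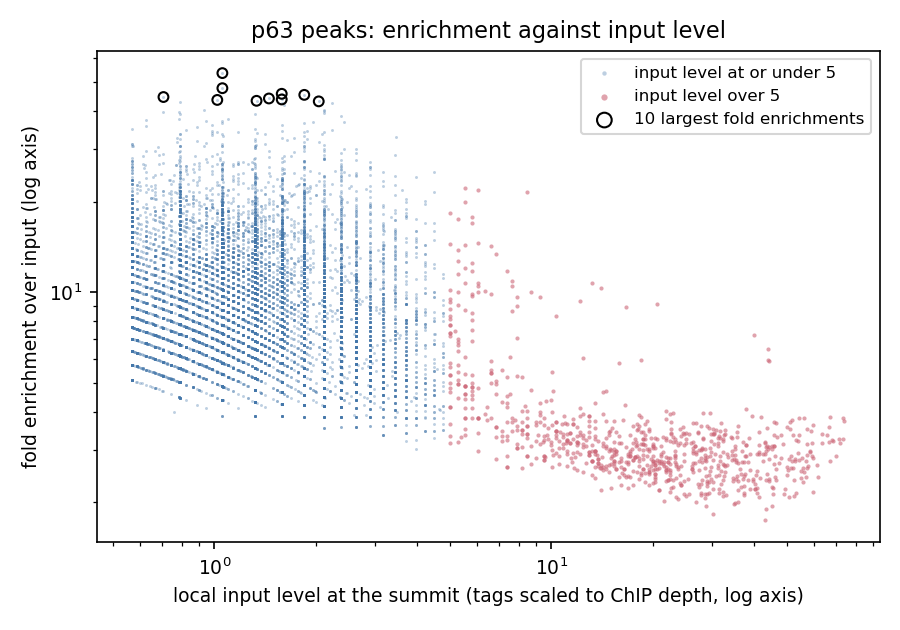
Fold enrichment over input of each of the 18548 p63 peaks (vertical log axis) against the local input level at its summit in scaled tags (horizontal log axis). Peaks over an input level of 5 (red) have a median fold of 3.07 and the others (blue) a median of 8.19; open circles mark the 10 peaks with the largest fold, at input levels of 0.706 to 2.04.

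Peaks were unevenly spread over the chromosomes. Relative to the extent from first to last peak, chromosomes 22, 20, 17 and 7 held 1.63, 1.54, 1.45 and 1.27 times their expected number of peaks. Chromosomes 13, 4, 18 and X held 0.607, 0.657, 0.736 and 0.781 times that number. In all, 9 of 23 chromosomes held more and 6 held fewer peaks than expected (exact binomial tests, adjusted p from 2.56e-36 for chromosome 4 to 0.0406 for chromosome 15 among these). With 5-Mb bins as the unit, 6 chromosomes were higher and 4 lower (permutation test). Chromosome 20 was among the higher ones with an adjusted permutation p of 0.0069. Chromosomes 6, 10, 15, 18 and 19 were no longer called, with adjusted permutation p of 0.295, 0.295, 0.628, 0.0778 and 0.419. On chromosome 18 the ratio hardly moved, at 0.734. At −log10 q of at least 10, 6 were higher and 6 lower. With the longest peak-free stretch subtracted from the extent, 9 were higher and 8 lower.

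With expected counts set by protein-coding genes, 10 chromosomes were higher and 8 lower. Of the 9 that were higher by extent, 3 were also higher by genes, chromosomes 7, 10 and 20. None of the 6 lower ones was also called lower. The largest departure was on chromosome 19, which changed from 1.18 to 0.325 times its expectation (exact binomial test, adjusted p = 3.91e-186). Its excess by extent was not called with bins as the unit (permutation test, adjusted p = 0.419). Nor was it called at −log10 q of at least 10 (exact binomial test, adjusted p = 0.126). Chromosome 17 changed from 1.45 to 0.678, chromosome 16 from 1.21 to 0.857, chromosome 1 from 1.13 to 0.928 and chromosome 22 from 1.63 to 0.860, whereas chromosome 13 rose from 0.607 to 1.16, chromosome 4 from 0.657 to 1.11 and chromosome 18 from 0.736 to 1.44. Chromosome 20 stayed above expectation at 1.22, chromosome 7 at 1.46 and chromosome 10 at 1.37. Of these, chromosome 10 was not called with bins as the unit (permutation test, adjusted p = 0.295). Across the 23 chromosomes, peaks per Mb at or under an input level of 5 rose with protein-coding genes per Mb (Spearman's rho = 0.74, permutation p = 0.00013, adjusted p = 0.00039 over 3 relations). Pearson's r was 0.55 (permutation p = 0.00639) and became 0.78 without the 2 chromosomes farthest from the median gene density.

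**Figure D2:**
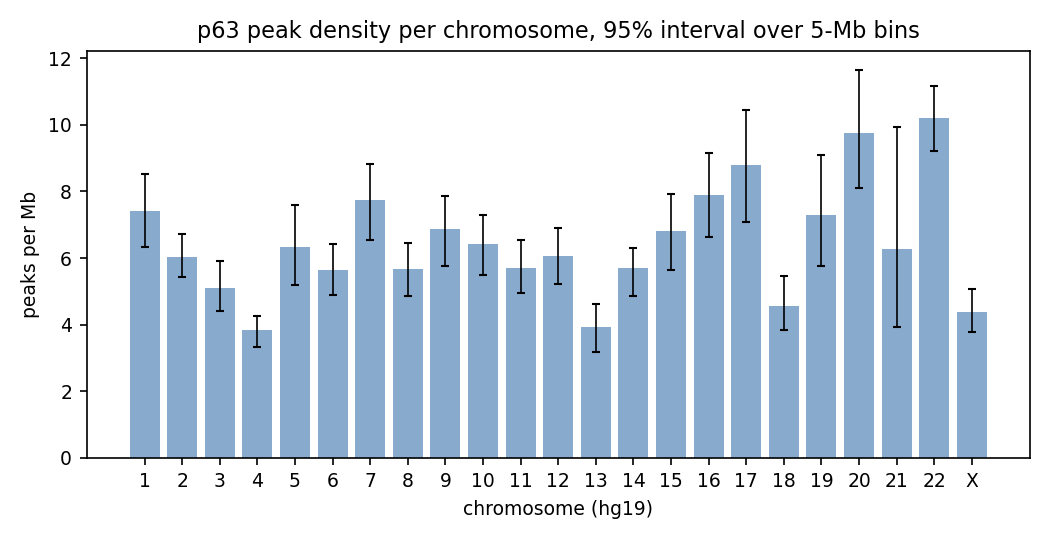
Peaks per Mb on each chromosome, peaks over an input level of 5 left out and the longest peak-free stretch subtracted from the extent. Bars start at 0 and lines are 95% intervals from resampling 5-Mb bins; chromosome 20 stands at 9.74 (8.10 to 11.6) and chromosome 4 at 3.83 (3.34 to 4.27).

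Chromosome 3 carries TP63, ACTL6A, SOX2 and WWTR1, and its long arm is often gained in squamous carcinomas. WWTR1 encodes TAZ, the paralogue of the Hippo effector YAP1, and SOX2 is a transcription factor of the squamous lineage. Chromosome 3 as a whole held fewer peaks than its extent predicted, 0.829 times (exact binomial test, adjusted p = 1.01e-09), and 1.04 times the gene-based expectation (adjusted p = 0.251). With bins as the unit the ratio to extent was 0.817 (permutation test, adjusted p = 0.0453), and with high-input peaks also left out it was 0.836 (permutation test, adjusted p = 0.0607). Its arms differed. The long arm held 6.58 peaks per Mb and the short arm 3.39, a ratio of 1.94 (95% interval, 1.58 to 2.40). By permutation of its 39 bins the p was 0.0001, the smallest 10000 permutations can give, and the adjusted p over 18 chromosomes was 0.0018. This p takes neighbouring bins as exchangeable and is too small where they share a density. With 1 Mb beside the peak-free stretch left out, the short arm had the lowest density of 41 arms, 3.34 peaks per Mb. The long arm, at 6.55, was not among the densest, which reached 11.6 on the long arm of chromosome 20. The ratio is therefore not by itself an excess of peaks on the long arm of chromosome 3. The median input level was 1.33 on the long and 1.06 on the short arm. Within the long arm the highest densities were distal, with 51, 55 and 50 peaks in the consecutive 5-Mb bins from 180000001 to 195000000. High density was not confined to these bins, as those from 150000001 to 160000000 held 49 and 44 peaks. The bin from 185000001 to 190000000 holds the strongest peak of the chromosome, at 43.7-fold. The next strongest on the long arm were at 181770125 to 181770543, with 30.4-fold (22.7 to 39.9), and at 152856398 to 152856801, with 30.2-fold (23.6 to 38.1). The strongest peak of the short arm, at 19350046 to 19350313, was enriched 30.7-fold (23.2 to 39.9). The 3 folds cannot be told apart at this depth.

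**Figure D3:**
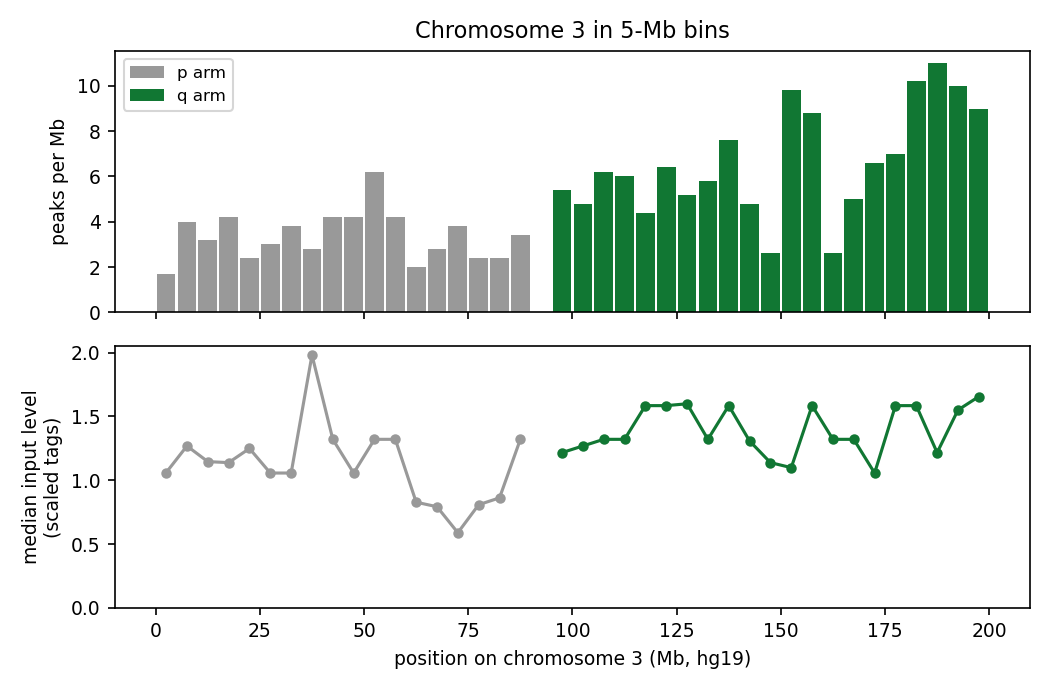
Chromosome 3 in 5-Mb bins: peaks per Mb (upper panel) and the median input level of those peaks in scaled tags (lower panel) against position in Mb on hg19. Short-arm bins are grey and long-arm bins green, peaks over an input level of 5 are left out, and density reaches 11.0 per Mb in the bin from 185000001 to 190000000.

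Arms also differed on 3 other chromosomes. Gene density per arm was not computed, here or for chromosome 3, so its part in arm differences was not tested. On chromosome 5, which carries WWC1, the gene of the Hippo activator KIBRA, the short arm was denser. It held 10.3 peaks per Mb against 4.99 on the long arm, a long-to-short ratio of 0.486 (0.373 to 0.720, adjusted permutation p = 0.0018). The median input level was 1.81 on its short and 1.06 on its long arm. The ratio was 0.671 on chromosome 6 (0.525 to 0.854, adjusted permutation p = 0.0168) and 0.660 on chromosome 7 (0.514 to 0.846, adjusted permutation p = 0.0292). On chromosome 7 the input level was 1.85 on the short and 1.32 on the long arm, while on chromosome 6 both arms stood at 1.06. The chromosome 7 difference was lost when each arm was scaled to the lowest input level, with a ratio of 0.803 (adjusted permutation p = 0.333), and the other 3 were kept. On chromosome 20 the ratio was 1.66 (1.27 to 2.12, adjusted permutation p = 0.0526), and it became 1.90 with the same scaling (adjusted permutation p = 0.0427). Chromosome 11, which carries YAP1, had a ratio of 0.966 (0.744 to 1.29, adjusted permutation p = 0.877).

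**Figure D4:**
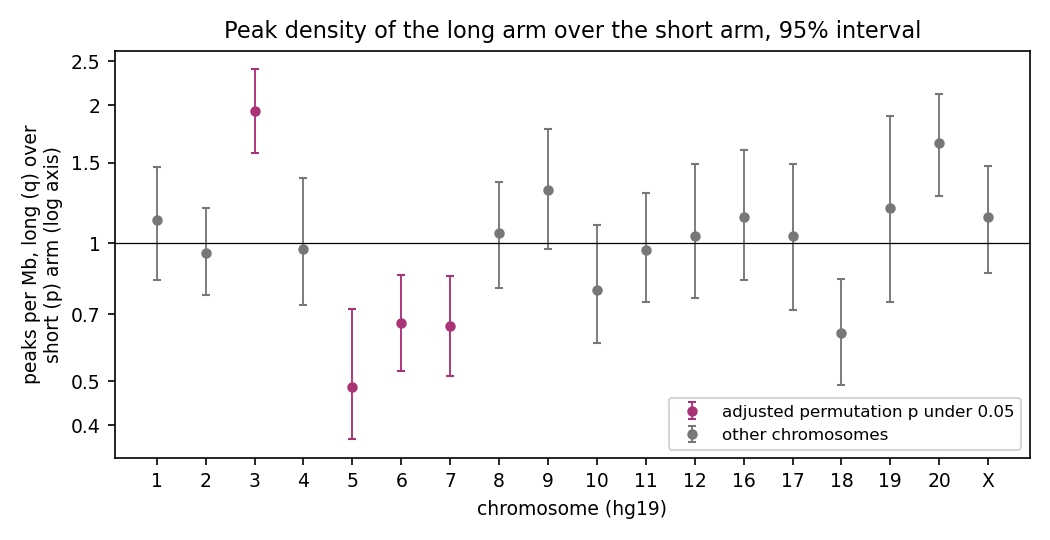
Peaks per Mb on the long arm divided by those on the short arm (log axis) for the 18 chromosomes with both arms assembled, peaks over an input level of 5 left out. Points are ratios and lines 95% intervals from resampling 5-Mb bins; chromosome 3 lies at 1.94 and chromosome 5 at 0.486.

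p63 summits lay closer together than chance placement gives. Of 17358 summits on chromosomes 1 to 22 and X at or under an input level of 5, 29.2% had another within 10 kb, against 12.05% (11.4% to 12.7%) when summits were shuffled over their chromosomes. Shuffling within 1-Mb windows gave 15.6% (14.9% to 16.3%). No shuffle of 1000 reached the observed share, a one-sided permutation p of 0.001, the smallest possible. Chains of summits no more than 10 kb apart gave 52 clusters of at least 5 summits, holding 314 summits. The largest lay on chromosome 1 between 228745930 and 228781951, with 26 summits, a highest fold of 12.8 and a median input level of 3.18. It rests on the input limit of 5, as 6 of the 26 summits stay at a limit of 3. The next, also on chromosome 1, had 9 summits each. One spanned 3607102 to 3634488 and ended in a peak of 43.6-fold, and one spanned 201252487 to 201281257 with a highest fold of 19.8. A cluster of 8 summits on chromosome 1 from 27179717 to 27194807 had the highest median fold of the 5 largest, 12.97. The 5 clusters of 7 summits lay on chromosome 17 from 71306785 to 71331901, on chromosome 7 from 55169171 to 55208673, on chromosome 11 from 1842013 to 1866354, on chromosome 6 from 36627246 to 36650874 and on chromosome 14 from 77407356 to 77426025. Their highest folds were 27.5, 24.9, 24.4, 22.1 and 11.2. At an input limit of 3 they kept 6, 6, 3, 7 and 6 of their 7 summits.

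Over whole megabases, the windows with most summits were on chromosome 1 from 228000001 to 229000000 with 38, on chromosome 1 from 201000001 to 202000000 with 31, and on chromosome 17 from 39000001 to 40000000 with 29. The window on chromosome 19 from 43000001 to 44000000 also held 29. The first of these windows had a median input level of 3.06, and at an input limit of 3 the second led with 31. The median fold of clustered summits was 8.07 against 8.24 in solitary summits, a log2 difference of -0.03 (-0.06 to -0.00298, permutation p = 0.0159). This comparison and those below treat summits as independent, although the clustered summits came from 2153 clusters. Their p-values are too small and their intervals too narrow where members of a cluster share a strength. With neighbours counted within 5 kb the difference was -0.0597 (-0.0858 to -0.0250, permutation p = 0.0001) and within 25 kb it was 0 (permutation p = 1). At −log10 q of at least 10 it was 0.0708 (0.0416 to 0.112, permutation p = 0.0001). The medians of −log10 q (permutation p = 0.334) and of pileup (permutation p = 1) did not differ past the threshold.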

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

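The tests in this part were chosen after the peak list was examined. The criterion for repeated sequence was written after its result was seen, and that for copy number gain before its test was run. Of the 587 peaks outside chromosomes 1 to 22 and X, 249 were over an input level of 5. The sequences named next, which enter the counts of all peaks and of high-input peaks but not the comparisons of chromosomes, arms or clustering, held peaks over the background level. The unlocalised chromosome 9 sequence gl000199 held 96 peaks at a median fold of 2.81 and a median input level of 16.8. The unplaced sequences gl000220, gl000214 and gl000225 held 60, 28 and 12 peaks at median input levels of 38.8, 22.1 and 23.8. The mitochondrial genome held 11 peaks with a median fold of 3.23 at an input level of 68.1. There are no control samples with peaks of their own, so these counts have no comparison.

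Of these 207 peaks, 204 are among the 852 over an input level of 5. None of the 207 entered the tests that follow, which used only peaks on the numbered chromosomes and X. The origin of the 207 peaks was therefore not tested. For high-input peaks on the numbered chromosomes and X, copy number gain of the surrounding megabase stays open. In the 185 windows of 1 Mb with such a peak, 1514 peaks lay at or under the limit. Their median input level was 1.212 times that of all peaks at or under the limit (bootstrap interval, 1.03 to 1.22). This meets the criterion first written against a gain. Leaving out peaks over the limit biases this first ratio down. With every peak of the windows, which biases it up, the ratio was 1.45 (1.35 to 1.82). Moreover, 432 of the 603 high-input peaks lie in windows with fewer than 5 peaks at or under the limit, and 132 in windows with none. These counts were made after the first ratio was seen, and that ratio says little of most high-input peaks. Reads of repeated sequence stacked on few reference copies stay open too, since the share of high-input peaks within 1 Mb of the longest peak-free stretch was 62.35%, but 29.55% at an input limit of 3 and 81.75% at 10. No biological explanation was tested, because the design has a single group.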

How the results depend on the processing

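Of 185 alternative settings over 34 results, 133 left the call as it was, or a count within 1.5 times; ratios of chromosomes not called by extent could cross 1 among these. No paired analysis was possible because each group has 1 library. The number of peaks fell from 18548 to 10777 at −log10 q of at least 10 and to 5806 at a fold of at least 10, by construction. The number of chromosomes that differed from their expectation was 15 and became 9 with 5-Mb bins permuted and high-input peaks left out. With gene-based expectations the ratio reversed for 11 of the 15 chromosomes called by extent, 1 (0.928), 3 (1.04), 4 (1.11), 6 (1.005), 13 (1.16), 15 (0.993), 16 (0.857), 17 (0.678), 18 (1.44), 19 (0.325) and 22 (0.860); the alternative's own construction, gene number in place of extent, is the cause. The share of high-input peaks was 8.44% at a limit of 3 and 3.53% at a limit of 10, and 29.55% and 81.75% of those on chromosomes 1 to 22 and X lay near the longest peak-free stretch. The chromosome 3 arm ratio ranged from 1.80 to 2.46 and stayed past the threshold in all 4 alternatives. The clustering ratio ranged from 1.15 to 3.35 and stayed past it in all 8. The strength difference of clustered summits was -0.0597 for neighbours within 5 kb, 0 for neighbours within 25 kb, 0 for pileup and -0.213 for −log10 q (permutation p = 0.334). It was 0.07079 at −log10 q of at least 10. Both lists are selected on q, and whether selection sets the direction was not tested. The planned promoter, motif, gene list and strength-by-location comparisons were not run, since no hg19 sequence or annotation was used. With 10380388 ChIP tags the median peak rests on 18 fragments, so the order of single peaks is not resolved.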

Other observations

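All relations below were chosen after the data were seen. The criteria for each explanation were written before its test was run, and for the 2 explanations of arm density they were made stricter after the values were seen. The arms with the highest median input level were 20p at 1.92, 7p at 1.85 and 5p at 1.81, and the lowest was 12p at 0.792. On 20p, 7p and 5p the median pileup was 23, 22 and 20 fragments, against 15 on 12p, while median folds were 7.78, 8.29, 7.72 and 7.74. The long arm of chromosome 20 had the highest density of the 41 arms (5 acrocentric chromosomes counted whole, 1 Mb beside the peak-free stretch left out), 11.6 peaks per Mb, and the short arm of chromosome 3 the lowest, 3.34. Alternative haplotype sequences held 69 peaks at a median fold of 8.27, and none of these was over an input level of 5.

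Across the 41 arms, peak density rose with input level (Spearman's rho = 0.52, interval 0.27 to 0.72, permutation p = 0.00068, adjusted p = 0.00136 over 4 relations; Pearson's r = 0.53, permutation p = 0.00047, and 0.51 without the 2 arms farthest from the median input). A candidate explanation is that more reads per site carry more sites past the q threshold on gained arms. With every arm scaled to the lowest input level, rho was 0.374 (0.09 to 0.61, permutation p = 0.0165) and Pearson's r was 0.31 (permutation p = 0.0503, not past the threshold), and given genes per Mb over 23 chromosomes the partial rho of input level and density was 0.4684 (0.011 to 0.83). Both rho values met the criteria first written against read number and against gene density, a rho of at least 0.3 and over 0.4 with an interval above 0. After they were seen the whole interval was required to pass these levels, which neither does, so both explanations stay open.

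Clustering of summits may reflect several binding sites within one regulatory region, a hypothesis that was not tested. Splitting of 1 enrichment into peaks with summits within 500 bp is argued against as the whole cause. Of adjacent summits within 10 kb, 12.71% (11.53% to 13.98%) were that close. With such summits merged, the share with a neighbour was still 2.22 times that of shuffles over the chromosome. Pieces of a broader enrichment could have summits farther apart, so splitting at that scale stays open. Peak density over megabases, as copy number or mappability would give, is argued against as the whole cause, since the observed share was 1.878 times that of shuffles within 1-Mb windows. Features of the sequence at a finer scale stay open.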
